A study of Homo sapiens with 33 samples.

How the data were processed

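Gene counts of 33 polyA RNA libraries from the U937 cell line were used, 1 file per library, covering control, C10KO and C8KO cells in media, PMA, PMA+LPS, PMA+TNF and PMA+ZCT. The deposited values are raw counts per gene for 58288 versioned Ensembl gene IDs. Per the labels, HISAT2 2.2.1, SAMtools 1.10 and HTSeq 0.11.1 were used with GRCh38. The labels state neither the annotation release, nor the strand setting, nor how reads that map to several places were treated, so counts of genes that overlap on opposite strands or have close paralogs can hold reads of their neighbours. Names and positions were found for 55661 IDs with their version and 2364 without it, and 263 IDs had none. All 33 libraries were kept, none was a copy of another, and groups were taken from the titles and labels. Total counts per library ran from 25616583 to 70982348.

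Genes were filtered with filterByExpr over the 15 groups (minimum count 10, minimum total 15), which left 21959. Models were fitted in R 4.3.3 with edgeR 4.0.16: TMM factors, 1 mean per group, glmQLFit and 2-sided glmQLFTest, with Benjamini-Hochberg adjustment within each comparison at 0.05. The labels state no statistical design. With 18 residual degrees of freedom, 3.78 prior degrees of freedom and a median biological coefficient of variation of 0.295, spread was pooled over groups because 12 of the 15 groups hold 2 libraries. Replicate numbers were tested as pairs and did not link libraries across conditions (213 correlations, median 0.001), so no block was used in the reported values. The labels do not say whether replicates are separate cultures, so p-values measure the spread between these libraries alone. Where a group had 0 counts, fold changes are given as at least the value at a floor of 3 counts over the group, and such floors cover counting error only.

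The comparisons were PMA against media and each stimulus against PMA in control cells, each knockout against control in each condition and averaged over the 5 conditions, C10KO against C8KO on average, and interaction terms of each knockout with each treatment. These 25 comparisons, the gene lists, the rule for naming genes and the alternatives were chosen before the data were examined, and 7 further comparisons were added after. The lists, 22 in all, held NF-kB targets, inflammatory cytokines, chemokines, interferon-stimulated genes, macrophage markers, promonocytic genes, cell cycle genes, death receptor and necroptosis genes, inflammasome genes, immediate early genes, stress response genes, cholesterol genes, MHC class II genes, matrix genes, glycolysis and hypoxia genes, mitochondrial mRNAs, histones, and markers of T and NK, B, epithelial, fibroblast and erythroid cells. Each list was counted over all genes and adjusted over the list alone, and tested against other genes with camera of limma 3.58.1 at a preset correlation of 0.01. Where that call held, its adjusted p with an estimated correlation is given, and fry was run as an alternative.

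Named genes were CASP10 and CASP8, the up to 8 genes with the largest rise and 8 with the largest fall per comparison (changed, mean log2 CPM of at least 1, every library of a group above every library of the other, or the same direction in each condition for averages, with names that are not clone identifiers), the up to 4 changed members of each list with the smallest p, and members of the cytokine, chemokine, death receptor and inflammasome lists as values. A few genes that this rule allows are not reported here. CPM used the TMM-scaled totals. Chromosome scans used the median of 20 neighbouring genes among 9389 protein-coding genes with mean log2 CPM of at least 3, with 200 shuffles of gene order. Segments run between the edges the scan gave. Edges first set by eye after the scan were narrower on chromosomes 4, 5 and 7, gave larger medians, and were replaced. Opposite-strand overlap was computed from annotated exons, with genes called covered at 80% of exon bases.

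On simulated counts for C10KO against control, genes changed 2-fold were recovered in 10% of cases with LPS, 46% with PMA and 96% for the average, and genes changed 4-fold in 80%, 86% and 100%, with 2, 3 and 4 unchanged genes called. Alternatives were RLE factors, DESeq2 1.42.0, no filter on low counts, a fit to the libraries of the compared groups alone, a replicate block, other list tests, and each library left out in turn. Leaving a group with 1 library assumed that it varied like the other groups. Added after the data were seen were averages without PMA alone and a fit without C10KO PMA replicate 3 and control PMA+ZCT replicate 2, which stood apart on a principal component. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.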

Results

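RNA sequencing was measured in U937 cells, a human promonocytic line that turns macrophage-like with phorbol myristate acetate (PMA). Control cells and cells with caspase-10 (C10KO) or caspase-8 (C8KO) knocked out, initiator caspases of the death receptor pathway, were compared to learn what each enzyme does in macrophages under immune stimulation. Each of the 3 genotypes was kept in media, given 10 nM PMA overnight, or given PMA and then 1 of 3 stimuli for 3 h. The stimuli were LPS at 1 ug/ml, TNF at 20 ng/ml, and ZCT, which is the caspase inhibitor Z-VAD-fmk at 20 uM for 30 min followed by TNF at 20 ng/ml and the translation inhibitor cycloheximide at 20 ng/ml. The 33 libraries form 15 groups, 3 of them (PMA alone) with 3 libraries and 12 with 2. The 9 PMA-alone libraries held 25616583 to 31955099 counts each, and the other 24 held 51856023 to 70982348. In what follows, log2 fold changes are given ± SE, levels are mean counts scaled to library size (CPM) ± SD over the libraries of a group, and a gene changed if its adjusted p was under 0.05 in edgeR.

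The 9 PMA-alone libraries stood apart from the rest in ways that treatment groups do not describe. Long noncoding RNA made up 2.05 to 2.18% of their counts, against 0.632 to 1.05% elsewhere. Genes whose exons lie at least 80% under exons of the opposite strand, 582 of the tested genes, summed to 6864 to 7808 CPM in these libraries and to 438 to 638 CPM in the other 24. MT-ND6, the mitochondrial mRNA coded on the strand opposite the others, ran from 714 to 1054 CPM against 6.07 to 48.2. The first principal component, with 39.8% of the variance, set PMA alone apart from all else, and the second, with 29.5%, set media apart. Every comparison of PMA alone with another condition therefore carries this difference, and counts over the 9383 tested genes without any opposite-strand overlap stand beside those of control cells.

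**Figure D1:**
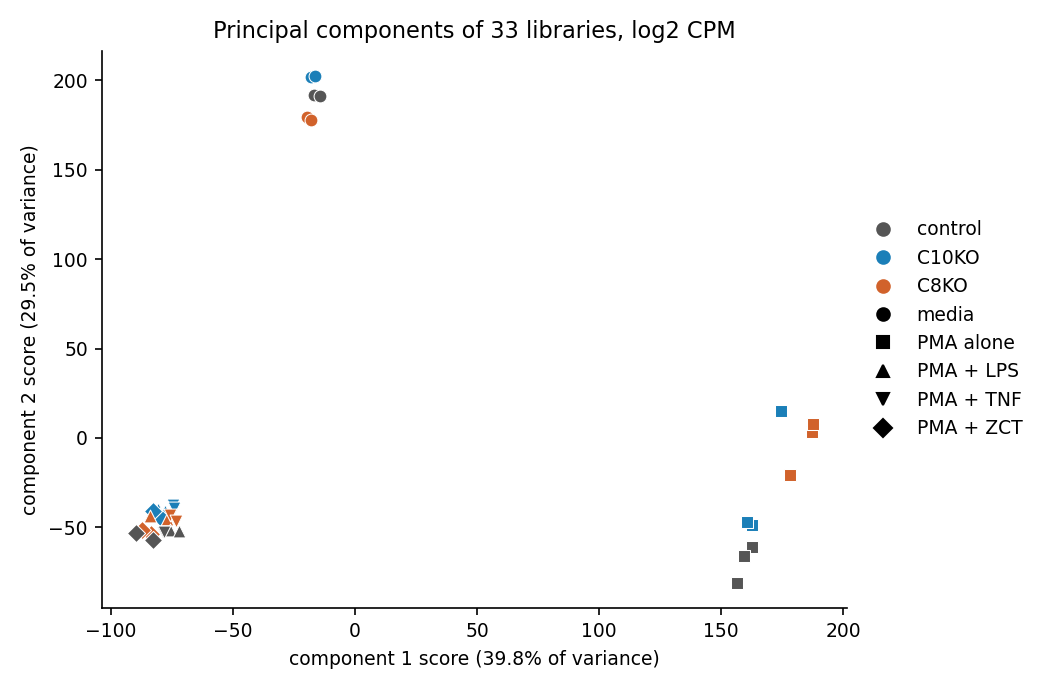
Scores of the 33 libraries on the first 2 principal components of log2 CPM, coloured by genotype and shaped by condition, with 1 point per library. The 9 PMA-alone libraries lie at 156.7 or above on component 1 (39.8% of variance), and all other libraries lie below 0.

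Transcripts of the targeted genes were not lost in the cells named after them. CASP10 (ENSG00000003400.14, chromosome 2, 201182881 to 201229406, GRCh38) stood at 12.6 ± 6.64 CPM in control and 9.83 ± 3.33 CPM in C10KO cells under PMA (n = 3 each). None of its 5 differences between C10KO and control passed the test, from -0.36 ± 0.31 in PMA to 0.27 ± 0.38 in media. CASP8 (ENSG00000064012.21, chromosome 2, 201233443 to 201287711) was at 44.1 ± 3.32 CPM in control and 35.8 ± 0.847 CPM in C8KO cells under LPS (n = 2 each). In C8KO cells, CASP8 was at -0.63 ± 0.14 under PMA alone (adjusted p = 0.00205) and at -0.31 ± 0.08 over the 5 conditions (adjusted p = 0.00474). CASP10 was higher in C8KO cells, by 1.47 ± 0.31 under PMA alone (adjusted p = 0.00101) and 0.78 ± 0.16 on average (adjusted p = 0.00134). In the 3 C8KO PMA-alone libraries, neighbouring genes from CASP8 onward were at -1.05 to -0.49 and those up to CASP10 at 0.65 to 1.72. Under PMA alone, CASP8 and CASP10 thus did not stand apart from their neighbours. Gene counts cannot show a frameshift, so these levels do not test whether protein was lost.

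In control cells, PMA raised single macrophage, cytokine and interferon genes strongly and lowered granule and cell division genes. Against media, 11981 of 21959 tested genes changed, 6476 higher and 5505 lower. CCL2, the monocyte chemoattractant, went from 45.5 ± 0.245 to 3519 ± 227 CPM (log2 6.27 ± 0.52), and OAS1, an antiviral enzyme (ENSG00000089127.12, chromosome 12, 112906777 to 112933222), from 0.426 ± 0.139 to 166 ± 35.2 CPM (8.60 ± 0.41), with 2 media and 3 PMA libraries. OLR1, a receptor for oxidised lipoprotein, VWF, TKTL1, XIRP1 and the chemerin receptor CMKLR1 had no counts in media and were at least 2974-fold, 2426-fold, 2736-fold, 2667-fold and 2471-fold higher, taking 3 counts over the group as the floor. Neutrophil granule proteases fell: PRTN3 (-7.07 ± 0.47) and ELANE (-5.98 ± 0.42), with MS4A3 of myeloid progenitors at -6.24 ± 0.42. Over genes without opposite-strand overlap, 4721 of 9383 changed, 2231 higher and 2490 lower. Scaling moves the balance of these calls, since the median log2 fold change of all genes was 0.12 with TMM factors and 0.29 with RLE factors.

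Many signalling and defence genes rose in control cells after PMA, and none of their lists held with an estimated correlation. All 31 of 31 interferon-stimulated genes rose (also 31 adjusted over the list alone, adjusted p = 0.185 with an estimated correlation), among them IRF7 (5.64 ± 0.33) and the RNA sensor IFIH1 (4.31 ± 0.21). NF-kB targets rose in 21 of 24 cases (also 21 adjusted over the list alone, adjusted p = 0.442 with an estimated correlation), inflammatory cytokines in 15 of 17 (also 15 adjusted over the list alone, adjusted p = 0.355 with an estimated correlation) and chemokines in 14 of 17 (15 adjusted over the list alone, adjusted p = 0.358 with an estimated correlation). TNF rose by 4.41 ± 0.49 and IL1RN, the antagonist of the IL-1 receptor, by 8.14 ± 0.65. Of the macrophage markers, 16 of 24 rose and 2 fell (17 and 2 adjusted over the list alone, adjusted p = 0.0819 with an estimated correlation), with the integrin chains ITGAX (5.78 ± 0.33) and ITGAM (5.34 ± 0.24) and the growth factor receptor CSF1R (6.73 ± 0.18) among the risen. Matrix remodelling genes rose in 15 of 18 cases (also 15 adjusted over the list alone, adjusted p = 0.185 with an estimated correlation), including the proteases MMP14 (6.91 ± 0.30) and MMP19 (8.90 ± 0.35). Immediate early genes had 18 higher and 2 lower of 24 (also 18 and 2 adjusted over the list alone, adjusted p = 0.358 with an estimated correlation). Inflammasome genes rose in 14 of 18 cases (14 higher and 1 lower adjusted over the list alone, adjusted p = 0.0863 with an estimated correlation), led by the DNA sensor AIM2 (7.06 ± 0.54). In the death receptor and necroptosis list, 14 rose and 4 fell of 24 (14 and 5 adjusted over the list alone, adjusted p = 0.264 for the list). MHC class II genes rose in 4 of 8 cases (also 4 adjusted over the list alone, adjusted p = 0.451 for the list). The stress response list had 10 higher and 4 lower of 18 (also 10 and 4 adjusted over the list alone, adjusted p = 0.588 for the list).

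Proliferation and metabolism lists moved downward or both ways under PMA. Cell cycle genes fell in 23 of 25 cases (also 23 adjusted over the list alone, adjusted p = 0.00864 with an estimated correlation), with the replication factors MCM7 (-2.26 ± 0.12) and PCNA (-2.15 ± 0.13) and the transcription factor MYBL2 (-2.04 ± 0.10). Promonocytic granule and progenitor genes had 1 higher and 11 lower of 15 (1 and 12 adjusted over the list alone, adjusted p = 0.061 with an estimated correlation). Cholesterol genes had 1 higher and 10 lower of 18 (also 1 and 10 adjusted over the list alone, adjusted p = 0.418 with an estimated correlation), INSIG1 at -1.86 ± 0.22 among the lower. Glycolysis and hypoxia genes split into 5 higher and 7 lower of 17 (also 5 and 7 adjusted over the list alone, adjusted p = 0.385 for the list). Replication-dependent histones had 1 higher and 6 lower of 14 (also 1 and 6 adjusted over the list alone, adjusted p = 0.102 for the list), and mitochondrially encoded mRNAs rose in 3 of 13 cases (1 adjusted over the list alone, adjusted p = 0.965 for the list), MT-ND6 included. Among markers of other cell types, 2 of 6 of the T and NK cell list rose (also 2 adjusted over the list alone, adjusted p = 0.36 for the list), the B cell list had 1 higher and 2 lower of 6 (also 1 and 2 adjusted over the list alone, adjusted p = 0.625 for the list), and 1 of 4 epithelial markers rose (also 1 adjusted over the list alone, adjusted p = 0.967 for the list). Fibroblast markers rose in 6 of 7 cases (also 6 adjusted over the list alone, adjusted p = 0.14 with an estimated correlation) and erythroid and platelet markers in 1 of 2 (2 adjusted over the list alone, adjusted p = 0.249 for the list).

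A comparison of PMA with TNF against media, which leaves out the PMA-alone libraries and was added after the data were seen, gave the same directions for the genes named here. Here 9741 of 21959 tested genes changed, 4473 higher and 5268 lower, and 4330 of the 9383 genes without overlap changed. Of the calls 45.9% were higher, but 53.2% with RLE factors and 53.3% in DESeq2, so the balance turns with scaling. OAS1 rose by 9.18 ± 0.43, IL1RN by 10.38 ± 0.71 and ITGAX by 6.02 ± 0.34, while MCM7 was at -2.42 ± 0.14 and ELANE at -6.03 ± 0.50. Cell cycle genes fell in 23 of 25 cases (24 adjusted over the list alone, adjusted p = 0.00545 with an estimated correlation) and interferon-stimulated genes rose in 31 of 31 (also 31 adjusted over the list alone, adjusted p = 0.0602 with an estimated correlation).

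LPS on top of PMA raised single inflammatory genes in control cells. Compared with PMA alone, 4889 of 21959 tested genes changed, 1651 higher and 3238 lower, and over genes without opposite-strand overlap 763 rose and 716 fell. ACOD1, which makes itaconate in activated macrophages, rose by 4.39 ± 0.67, the cholesterol exporter ABCA1 by 2.60 ± 0.47, TNIP3 by 2.76 ± 0.62 and IL1RN by 2.01 ± 0.43 (327 ± 46.2 to 1320 ± 184 CPM, n = 3 and 2). NF-kB targets rose in 4 of 24 cases (3 adjusted over the list alone, adjusted p = 0.643 with an estimated correlation), CD83 at 0.99 ± 0.29 among them. Cholesterol genes rose in 8 of 18 (10 adjusted over the list alone, adjusted p = 0.187 with an estimated correlation), with INSIG1, a sterol sensor, at 0.98 ± 0.22. The protease inhibitor TIMP1 rose by 0.97 ± 0.23. Among the furthest falls, the antisense RNA ARAP1-AS1, whose exons lie under exons of the opposite strand, was at least 986-fold lower, and MT-ND6 was at -5.55 ± 0.25. Without control PMA+LPS replicate 1 or 2 the count was 2790 or 2785.

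TNF and ZCT moved more genes than LPS did in count, against the same 3 PMA libraries. With TNF, 6335 of 21959 tested genes changed, 2535 higher and 3800 lower (1168 higher and 956 lower of those without overlap), and without control PMA+TNF replicate 1 or 2 the count was 4052 or 3722. IL1RN rose by 2.23 ± 0.43, TM4SF1, a membrane protein, by 2.38 ± 0.23, the monocyte attractant CCL7 by 1.54 ± 0.50, and NFKBIA, the inhibitor of NF-kB that NF-kB itself induces, by 0.98 ± 0.30. NF-kB targets rose in 6 of 24 cases (also 6 adjusted over the list alone, adjusted p = 0.709 with an estimated correlation) and interferon-stimulated genes in 7 of 31 (also 7 adjusted over the list alone, adjusted p = 0.633 with an estimated correlation). With ZCT, 9270 of 21959 tested genes changed, 4246 higher and 5024 lower (1984 higher and 1512 lower of those without overlap). ISG15, a ubiquitin-like interferon product (ENSG00000187608.8, chromosome 1, 1001138 to 1014540), rose from 700.4 ± 110.3 to 2819 ± 1419 CPM (2.01 ± 0.29), IFI6 by 2.39 ± 0.37 and BST2 by 1.66 ± 0.17, within 20 of 31 interferon-stimulated genes (also 20 adjusted over the list alone, adjusted p = 0.418 with an estimated correlation). The neutrophil attractants CXCL8 and CXCL2 rose by 2.25 ± 0.83 and 2.49 ± 0.72, among 8 of 17 chemokines (also 8 adjusted over the list alone, adjusted p = 0.635 with an estimated correlation). Death receptor genes had 15 higher and 0 lower of 24 (also 15 adjusted over the list alone, adjusted p = 0.137 with an estimated correlation), with the adaptor FADD at 1.02 ± 0.14 and CASP8 at 0.46 ± 0.16 (adjusted p = 0.0231). In ZCT against TNF, a comparison without PMA-alone libraries described below, 0 of 31 interferon-stimulated and 0 of 24 death receptor genes changed. Adjusted over each list alone, 2 and 7 were higher, with list medians of 0.653 and 0.34. Mitochondrial mRNAs fell in 12 of 13 cases with TNF (also 12 adjusted over the list alone, adjusted p = 0.354 with an estimated correlation) and 10 of 13 with ZCT (also 10 adjusted over the list alone, adjusted p = 0.479 with an estimated correlation).

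Shared calls between stimuli were many: LPS and TNF raised 1402 genes and lowered 2907 in common, LPS and ZCT 1382 and 2865, and TNF and ZCT 2263 and 3382, with 0, 4 and 2 genes in opposite directions. The Pearson r between their differences was 0.882 to 0.907, and simulated unchanged groups against the same PMA libraries gave 0.431 to 0.443. All 3 comparisons share the PMA-alone libraries and their opposite-strand difference. Direct comparisons of stimuli, added after the data were seen, do not involve PMA alone. LPS against TNF had 0 changed genes in edgeR, with 1030 at an unadjusted p under 0.05 and 45 by DESeq2, and 1 to 3 without each library in turn. Mitochondrially encoded mRNAs, a list for RNA quality, were higher with LPS in 12 of 13 cases adjusted over the list alone (median log2 fold change 0.75, adjusted p = 0.0596 with an estimated correlation). The treatment protocol in the labels uses the LPS wording for the TNF cells too, and the groups follow the titles, so what the absence of a difference means stays open. ZCT against TNF had 228 changed genes, 157 higher and 71 lower: DNAJB9, a chaperone of the endoplasmic reticulum, was lower (-1.89 ± 0.22), and the lipid droplet protein PLIN2 (1.72 ± 0.27) and the sterol enzyme HMGCS1 (0.89 ± 0.14) were higher. That count was 4237 without control PMA+ZCT replicate 1, and 1, 4 and 5 without control PMA+TNF replicate 1, control PMA+TNF replicate 2 and control PMA+ZCT replicate 2.

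In media, C10KO cells differed from control cells in few genes. Against control, 245 of 21959 tested genes changed, 161 higher and 84 lower. The scavenger receptor CD36 fell to 1.16 ± 0.0727 from 27.9 ± 0.406 CPM (-4.59 ± 0.24, n = 2 each) and the metalloprotease ADAM12 was at -2.17 ± 0.54. SNRPN, an imprinted splicing factor gene, was higher by 10.72 ± 0.48, MAGED1 by 8.62 ± 0.47, and DNAJC15 and SNX25, absent from control media libraries, by at least 428-fold and 268-fold. Cholesterol genes were higher in 4 of 18 cases (5 adjusted over the list alone, adjusted p = 0.00864 with an estimated correlation), with HMGCS1 at 1.43 ± 0.14 and MSMO1 at 1.71 ± 0.17. HMGCS1 lies in a chromosome 5 segment, described below, that was at 0.33 and 0.35 in the C10KO media libraries. MSMO1 lies in a chromosome 4 segment at 0.79 and 0.76. Glycolysis and hypoxia genes were higher in 4 of 17 (8 higher and 1 lower adjusted over the list alone, adjusted p = 0.0228 with an estimated correlation), including the vasodilator peptide ADM (5.93 ± 0.99). Interferon-stimulated genes were higher in 4 of 31 (6 adjusted over the list alone, adjusted p = 0.442 with an estimated correlation). CCL2 was lower, at 11.4 ± 0.188 CPM against 45.5 ± 0.245 in control cells. Each of the 4 libraries left out in turn gave 109 to 133 changed genes.

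With PMA alone, interferon-stimulated genes were lower and cell cycle genes higher in C10KO than in control cells. Of 21959 tested genes, 1621 changed, 914 higher and 707 lower (401 and 364 of those without opposite-strand overlap). Interferon-stimulated genes fell in 27 of 31 cases (29 adjusted over the list alone, adjusted p = 0.0113 with an estimated correlation): ISG15 went from 700.4 ± 110.3 to 88.8 ± 43.5 CPM (-2.98 ± 0.28, n = 3 each), and IFIT1 (-3.12 ± 0.33) and USP18 (-2.77 ± 0.28) fell as well. Cell cycle genes rose in 15 of 25 cases (20 adjusted over the list alone, adjusted p = 0.000603 with an estimated correlation), with MCM7 at 1.25 ± 0.11, PCNA at 1.16 ± 0.12 and MYBL2 at 1.14 ± 0.09. Cholesterol genes rose in 8 of 18 (12 adjusted over the list alone, adjusted p = 0.0228 with an estimated correlation). Chemokines fell in 3 of 17 cases (1 higher and 3 lower adjusted over the list alone, adjusted p = 0.589 with an estimated correlation), CCL8 (-2.99 ± 0.82), CCL7 (-2.35 ± 0.47) and CXCL10 (-1.32 ± 0.29). SIGLEC1, an interferon-induced sialic acid receptor (-3.35 ± 0.51), TKTL1 (-4.37 ± 0.48) and ADAM12 (-3.89 ± 0.43) fell. Matrix genes fell in 6 of 18 cases (7 adjusted over the list alone, adjusted p = 0.231 with an estimated correlation) and macrophage markers had 1 higher and 5 lower of 24 (1 and 8 adjusted over the list alone, adjusted p = 0.187 with an estimated correlation). C10KO PMA replicate 3 had 186 CPM of IL1B where replicates 1 and 2 had 9036 and 9851, and without control PMA replicate 1 the count of changed genes was 932.

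Under LPS, C10KO cells had higher cell cycle and cholesterol genes than control cells. Here 2342 of 21959 tested genes changed, 1441 higher and 901 lower, and each of the 4 libraries left out in turn gave 907 to 1292. Cell cycle genes were higher in 23 of 25 cases (24 adjusted over the list alone, adjusted p = 2.86e-05 with an estimated correlation): MYBL2 by 1.94 ± 0.11, PCNA by 1.88 ± 0.15 and MCM7 by 1.72 ± 0.13. Cholesterol genes were higher in 11 of 18 (16 adjusted over the list alone, adjusted p = 0.00843 with an estimated correlation), HMGCS1 going from 87 ± 6.22 to 318 ± 5.15 CPM (1.87 ± 0.14, n = 2 each). Interferon-stimulated genes were lower in 23 of 31 (26 adjusted over the list alone, adjusted p = 0.146 with an estimated correlation), with STAT2 at -1.92 ± 0.24. The cytokines IL23A and LTB rose by 2.28 ± 0.64 and 2.09 ± 0.62, the chemokine CXCL16 by 1.61 ± 0.35, and the NF-kB subunits NFKB1 and NFKB2 by 0.97 ± 0.20 and 1.15 ± 0.26 among 3 of 24 NF-kB targets (5 adjusted over the list alone, adjusted p = 0.659 with an estimated correlation). TNF mRNA was at 1068 ± 152 CPM against 454 ± 19.4 in control, a log2 difference of 1.23 ± 0.44 (adjusted p = 0.0781), and IL1B at 25420 ± 3017 against 13440 ± 351 (adjusted p = 0.646). Mitochondrial mRNAs were lower in 7 of 13 cases (10 adjusted over the list alone, adjusted p = 0.277 with an estimated correlation).

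TNF and ZCT gave C10KO differences in the same lists. With TNF, 795 of 21959 tested genes changed, 537 higher and 258 lower, and each of the 4 libraries left out in turn gave 382 to 443. Interferon-stimulated genes were lower in 17 of 31 cases (25 adjusted over the list alone, adjusted p = 0.0488 with an estimated correlation) and cell cycle genes higher in 22 of 25 (23 adjusted over the list alone, adjusted p = 1.84e-05 with an estimated correlation). HMGCS1 was higher by 2.55 ± 0.15 among 7 of 18 cholesterol genes (10 adjusted over the list alone, adjusted p = 0.00843 with an estimated correlation), and FABP4, a fatty acid carrier of macrophages (-3.86 ± 1.04), was lower. With ZCT, 1110 of 21959 tested genes changed, 663 higher and 447 lower, but 4 in a fit to the libraries of these groups alone and 1877 by DESeq2. Of these calls 59.7% were higher, but 54.8% with RLE factors and 49.7% in DESeq2. The lists had 22 of 31 interferon-stimulated genes lower (26 adjusted over the list alone, adjusted p = 0.0339 with an estimated correlation), 19 of 25 cell cycle genes higher (23 adjusted over the list alone, adjusted p = 2.29e-05 with an estimated correlation) and 9 of 18 cholesterol genes higher (10 adjusted over the list alone, adjusted p = 0.00748 with an estimated correlation). RSAD2, the antiviral enzyme viperin (-3.21 ± 0.61), CXCL10 (-1.71 ± 0.36) and the necroptosis effector MLKL (-0.78 ± 0.12) were lower. The ZCT count was 3555 without control PMA+ZCT replicate 1, 650 without C10KO PMA+ZCT replicate 1 and 578 without C10KO PMA+ZCT replicate 2.

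Averaged over the 5 conditions, C10KO cells showed lower interferon genes, higher cell cycle genes and higher cholesterol genes. In all, 3728 of 21959 tested genes changed, 2092 higher and 1636 lower. Cholesterol genes were higher in 16 of 18 cases (also 16 adjusted over the list alone, adjusted p = 0.00219 with an estimated correlation), with HMGCS1 at 1.77 ± 0.06 and MSMO1 at 1.71 ± 0.08. HMGCS1 and MSMO1 lie in segments of chromosomes 5 and 4, described below, with medians of 0.36 and 0.83 in C10KO cells. Their values may include these shifts. Cell cycle genes were higher in 24 of 25 (25 adjusted over the list alone, adjusted p = 2.29e-05 with an estimated correlation), with MYBL2 at 1.21 ± 0.05 and MCM7 at 1.17 ± 0.06. In media, however, 0 of the 25 cell cycle genes changed, with a median log2 fold change of -0.00959. Interferon-stimulated genes were lower in 23 of 31 (24 adjusted over the list alone, adjusted p = 0.0381 with an estimated correlation), with ISG15 at -1.78 ± 0.14. In media 4 of that list were higher instead, and with LPS the list did not hold with an estimated correlation (adjusted p = 0.146). MLKL (-0.50 ± 0.05) was lower, and CASP8 was at -0.24 ± 0.08 (adjusted p = 0.0265). Some of the largest differences ran one way in all conditions, such as SNRPN (9.35 ± 0.20), MAGED1 (8.39 ± 0.21) and B4GALNT1, a ganglioside synthase (4.42 ± 0.28), against ADAM12 (-3.78 ± 0.22) and ZDHHC21 (-2.66 ± 0.15). Of the calls 56.1% were higher, but 48.9% with RLE factors and 47% in DESeq2. Without the PMA-alone libraries 3955 genes changed, 3149 of them among the 3728 and in the same direction. In each of the 5 conditions separately, 62 genes were higher and 21 lower, 83 together. Far fewer were called in all 5 in a fit to the libraries of the compared groups alone. Across genes, which are not independent replicates, the C10KO log2 fold changes of any pair of conditions had a median Pearson r of 0.194 (0.117 to 0.256) and a median Spearman rho of 0.224 (0.004 to 0.381) over the 10 pairs, no library being shared.

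**Figure D2:**
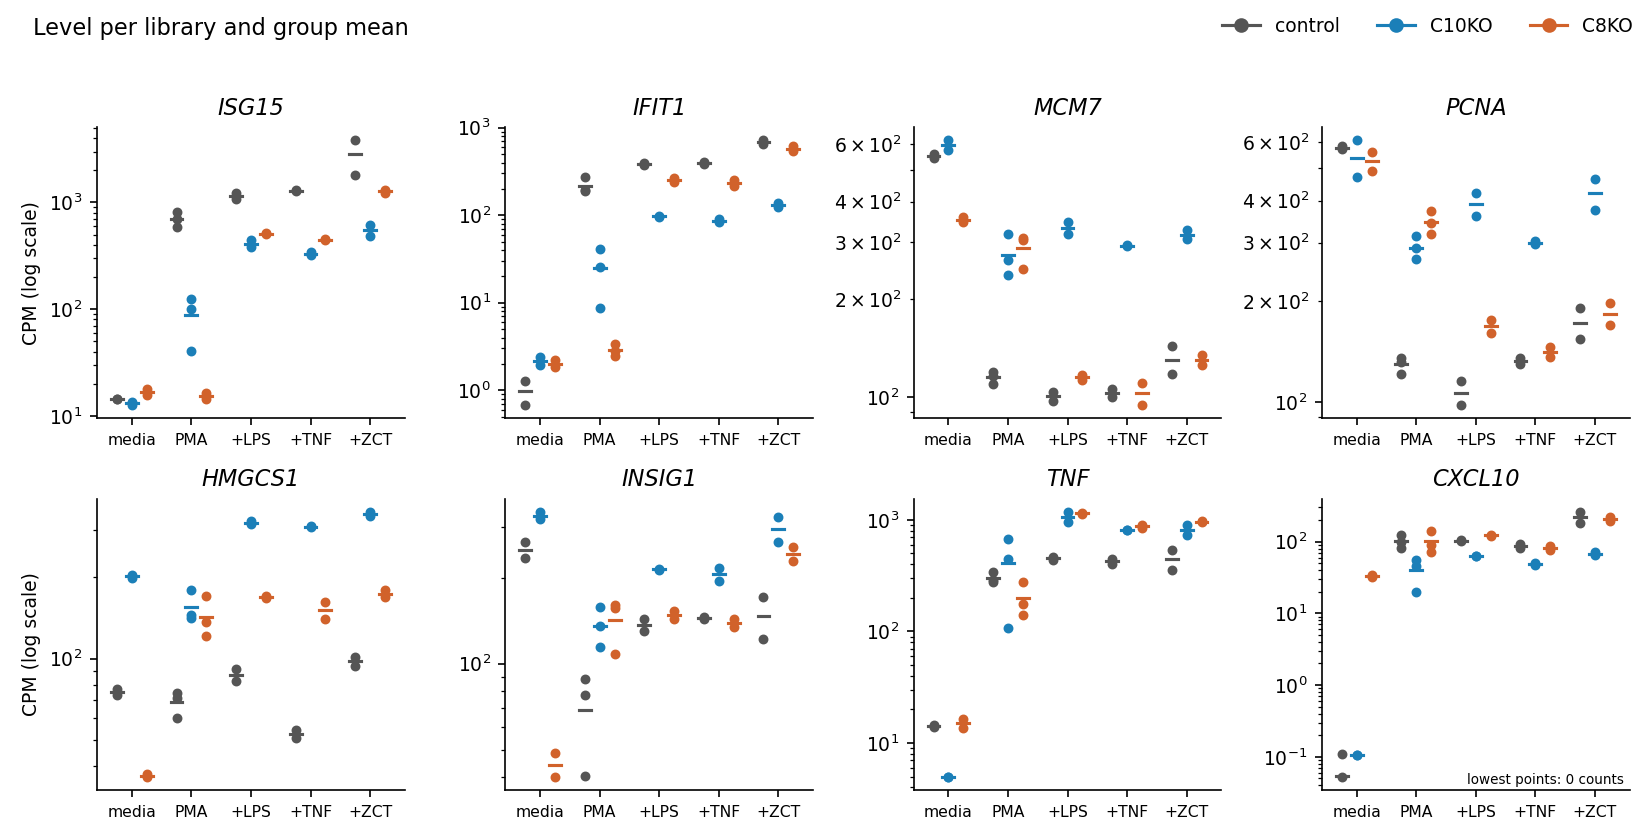
CPM on a log axis of 8 genes in each library (points) with group means (bars), for control, C10KO and C8KO cells in the 5 conditions. Under PMA alone the ISG15 mean was 700.4 CPM in control, 88.8 in C10KO and 15.3 in C8KO cells.

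C8KO cells in media had less cholesterol gene expression and more of several inflammatory genes than control cells. Against control, 430 of 21959 tested genes changed, 281 higher and 149 lower. Cholesterol genes were lower in 14 of 18 cases (17 adjusted over the list alone, adjusted p = 1.97e-05 with an estimated correlation): INSIG1 went from 250.3 ± 22.5 to 44.4 ± 5.92 CPM (-2.50 ± 0.26, n = 2 each), with CYP51A1 at -1.51 ± 0.13 and IDI1 at -1.46 ± 0.15. CYP51A1 lies in a chromosome 7 segment, described below, that was at -0.52 and -0.5 in these C8KO libraries. CXCL10, an interferon-induced chemokine, was higher by 9.21 ± 0.59 (0.0545 ± 0.0771 to 33.2 ± 1.19 CPM) and MMP9, a gelatinase, by 7.16 ± 0.69 (0.487 ± 0.392 to 69.3 ± 0.905). NF-kB targets were higher in 3 of 24 cases (5 adjusted over the list alone, adjusted p = 0.266 with an estimated correlation), with the feedback inhibitor TNFAIP3 at 1.82 ± 0.29 and BIRC3 at 2.75 ± 0.46. Interferon-stimulated genes were higher in 6 of 31 (7 adjusted over the list alone, adjusted p = 0.249 with an estimated correlation), with OAS2 at 3.69 ± 0.49. Glycolysis genes were higher in 4 of 17 (also 4 adjusted over the list alone, adjusted p = 0.039 with an estimated correlation) and inflammasome genes in 2 of 18 (5 adjusted over the list alone, adjusted p = 0.044 with an estimated correlation). SNX19, a sorting nexin, was at least 122-fold lower, and DNAJC15, absent from control media libraries, at least 722-fold higher. Each of the 4 libraries left out in turn gave 232 to 250 changed genes.

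With PMA alone, C8KO cells had far lower interferon genes and higher cell cycle genes than control cells. Of 21959 tested genes, 5434 changed, 2758 higher and 2676 lower (1170 and 1276 of those without opposite-strand overlap). Interferon-stimulated genes were lower in 28 of 31 cases (also 28 adjusted over the list alone, adjusted p = 0.0228 with an estimated correlation): ISG15 (-5.51 ± 0.32, 700.4 ± 110.3 to 15.3 ± 1.01 CPM, n = 3 each), OAS1 (-5.10 ± 0.28) and IFI35 (-9.01 ± 0.48). Macrophage markers had 3 higher and 10 lower of 24 (also 3 and 10 adjusted over the list alone, adjusted p = 0.056 for the list), with the haemoglobin scavenger CD163 at -3.74 ± 0.47 and CSF1R at -2.46 ± 0.12 lower and CD36 higher (1.76 ± 0.17). Matrix genes had 3 higher and 10 lower of 18 (4 and 10 adjusted over the list alone, adjusted p = 0.353 with an estimated correlation), MMP7 at -5.52 ± 0.51 among the lower. Chemokines had 1 higher and 6 lower of 17 (also 1 and 6 adjusted over the list alone, adjusted p = 0.65 with an estimated correlation), with CXCL3 at 6.85 ± 1.28 and CCL8 at -5.84 ± 0.98. The cytokine genes IL1A (-4.73 ± 0.96) and IL1RN (-2.20 ± 0.40) fell, as did CASP1, the inflammasome protease (-1.54 ± 0.23), among 7 of 18 inflammasome genes (1 higher and 7 lower adjusted over the list alone, adjusted p = 0.277 with an estimated correlation). Cell cycle genes were higher in 17 of 25 cases (19 adjusted over the list alone, adjusted p = 0.00843 with an estimated correlation), with MCM3 at 1.84 ± 0.17 and PCNA at 1.41 ± 0.12, and CD74, the MHC class II chaperone, rose by 3.73 ± 0.45. Cholesterol genes had 8 higher and 1 lower of 18 (also 8 and 1 adjusted over the list alone, adjusted p = 0.261 with an estimated correlation). These 3 C8KO libraries differed from the other 8 C8KO libraries in whole chromosomes, with medians of 0.59 to 0.86 on chromosome 18 and -0.5 to -0.41 on chromosome 21 relative to control libraries of their condition. C8KO PMA replicates 1 and 3 had 857 and 553 CPM of IL1B and replicate 2 had 7317.

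After stimulation, C8KO cells differed from control cells in fewer genes than under PMA alone, and shared genes stood out across LPS, TNF and ZCT. The counts were 785 with LPS (426 higher, 359 lower), 409 with TNF (197, 212) and 500 with ZCT (244, 256). With LPS 54.3% of calls were higher, but 48.1% with RLE factors and 49.3% in DESeq2. The neutrophil chemokine CXCL3 was higher by 6.15 ± 1.19, 6.75 ± 1.26 and 6.21 ± 1.20 in the 3 conditions, and the collagenase MMP1 by 3.97 ± 0.66, 3.58 ± 0.65 and 3.87 ± 0.66. The tetraspanin CD81 was lower, at -4.49 ± 0.69, -4.36 ± 0.67 and -4.48 ± 0.68, and the collagen chain COL6A3, at -2.56 ± 0.42, -2.30 ± 0.42 and -2.18 ± 0.42. Interferon-stimulated genes were lower in 9 of 31 cases with LPS (17 adjusted over the list alone, adjusted p = 0.239 with an estimated correlation), 11 of 31 with TNF (15 adjusted over the list alone, adjusted p = 0.159 with an estimated correlation) and 4 of 31 with ZCT (12 adjusted over the list alone, adjusted p = 0.353 with an estimated correlation), HERC5, a ligase for ISG15, at -1.54 ± 0.28 with TNF. Immediate early genes were higher in 3 of 24 with LPS (4 adjusted over the list alone, adjusted p = 0.353 with an estimated correlation) and 5 of 24 with ZCT (7 adjusted over the list alone, adjusted p = 0.238 with an estimated correlation), the nuclear receptor NR4A1 by 2.02 ± 0.33 with ZCT. HMGCS1 was higher by 0.96 ± 0.14, 1.52 ± 0.14 and 0.83 ± 0.14, and cell cycle genes in 3 of 25 cases with LPS (7 adjusted over the list alone, adjusted p = 0.0289 with an estimated correlation). TNF mRNA with LPS was at 1142 ± 15.9 CPM against 454 ± 19.4 (adjusted p = 0.104). Each of the 4 libraries left out in turn gave 237 to 337 with LPS and 163 to 174 with TNF, while ZCT gave 1885 and 923 without control PMA+ZCT replicates 1 and 2 and 197 and 205 without C8KO PMA+ZCT replicates 1 and 2.

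Averaged over the 5 conditions, 3690 genes differed between C8KO and control cells, 2011 higher and 1679 lower. MMP1 was higher by 3.49 ± 0.30, MMP9 by 2.70 ± 0.24, the lymphotoxin subunit LTB by 1.96 ± 0.26 and CD36 by 0.96 ± 0.09, and SNX19 was lower (-10.38 ± 0.24) with CD81 at -4.88 ± 0.36. NF-kB targets were higher in 10 of 24 cases (11 adjusted over the list alone, adjusted p = 0.585 with an estimated correlation), with BIRC3 at 1.32 ± 0.18 and NFKB2 at 0.53 ± 0.11, and TNF was higher by 0.59 ± 0.19. Interferon-stimulated genes had 1 higher and 25 lower of 31 (2 and 25 adjusted over the list alone, adjusted p = 0.0637 with an estimated correlation), with ISG15 at -1.82 ± 0.14. PMA alone carries much of this, with 28 of the list lower there, against 6 higher in media and 9, 11 and 4 lower with LPS, TNF and ZCT. Cell cycle genes were higher in 18 of 25 (22 adjusted over the list alone, adjusted p = 0.00864 with an estimated correlation). Most of that list was higher under PMA alone, against 3, 1 and 0 of 25 with LPS, TNF and ZCT, so PMA alone carries much of this too. Glycolysis genes had 6 higher and 1 lower of 17 (9 and 1 adjusted over the list alone, adjusted p = 0.204 with an estimated correlation). Of the calls 54.5% were higher, but 49.6% with RLE factors and 48.9% in DESeq2. Without the PMA-alone libraries 3341 genes changed, 2435 of them among the 3690 and in the same direction. In each of the 5 conditions separately, 64 genes were higher and 21 lower, and far fewer in a fit to the libraries of the compared groups alone. Across genes, the median Pearson r between conditions was 0.223 (0.111 to 0.319) and the median Spearman rho 0.188 (-0.002 to 0.383).

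**Figure D3:**
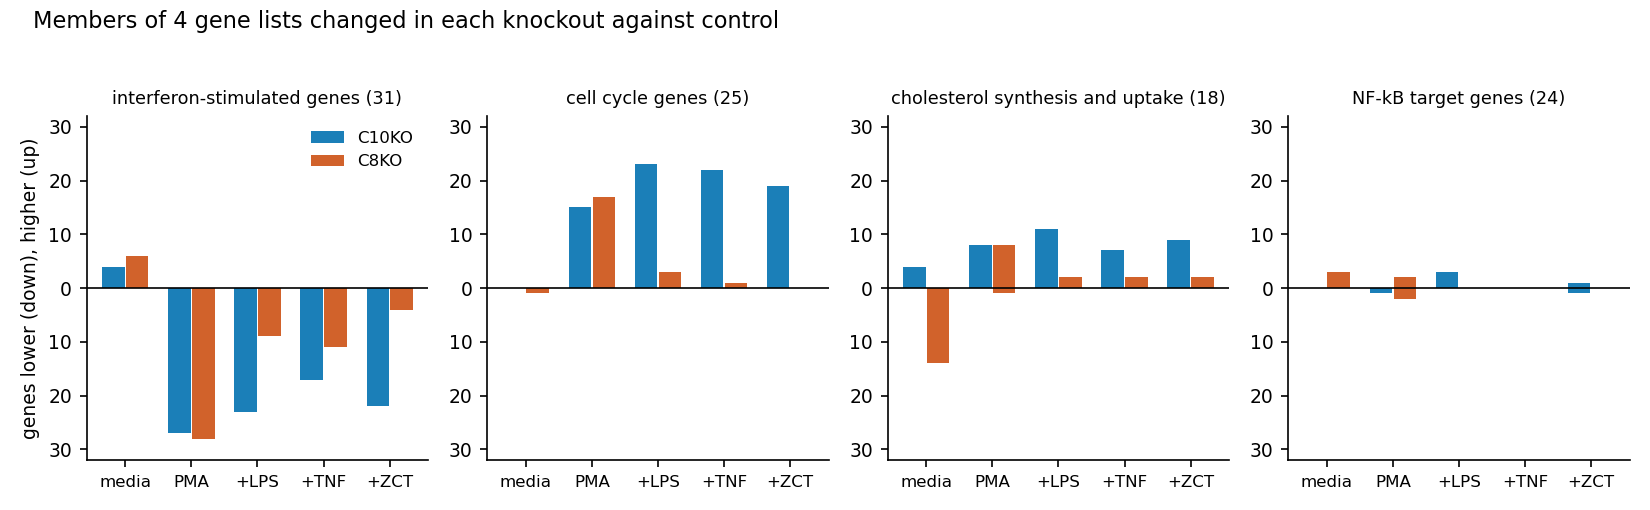
Number of members of 4 gene lists that were higher (bars up) or lower (bars down) in C10KO and C8KO cells than in control cells of the same condition, with the number measured in brackets. Interferon-stimulated genes under PMA alone were lower in 27 and 28 of 31 cases.

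Compared with each other, C10KO cells had higher cell cycle and cholesterol genes than C8KO cells. Averaged over the 5 conditions, 3299 of 21959 tested genes changed, 1712 higher and 1587 lower. Without the PMA-alone libraries, a fit added after the data were seen, 3905 genes changed, 1936 higher and 1969 lower, 2613 of them among the 3299 and in the same direction. Cell cycle genes were higher in C10KO cells in 22 of 25 cases (23 adjusted over the list alone, adjusted p = 0.000302 with an estimated correlation), with MCM7 at 1.00 ± 0.06 and MYBL2 at 0.97 ± 0.05. Cholesterol genes were higher in 16 of 18 (17 adjusted over the list alone, adjusted p = 0.000573 with an estimated correlation), with HMGCS1 (adjusted p = 1.77e-11) and the regulator SREBF2 at 0.62 ± 0.05. MCM7 lies in the chromosome 7 segment, described below, that was at -0.52 to -0.41 in the 8 C8KO libraries other than PMA alone. HMGCS1 lies in the chromosome 5 segment, with a median of 0.36 in C10KO cells. The values of MCM7 and HMGCS1 may include these shifts. CXCL16 was higher by 2.40 ± 0.16 and lysozyme, LYZ, by 1.11 ± 0.06, while CD36 (-2.82 ± 0.09), CXCL10 (-2.58 ± 0.18), MMP1 (-3.51 ± 0.31) and IFI44 (-4.00 ± 0.40) were lower. Histones were lower in 6 of 14 cases (also 6 adjusted over the list alone, adjusted p = 0.193 with an estimated correlation), and matrix genes had 1 higher and 6 lower of 18 (2 and 7 adjusted over the list alone, adjusted p = 0.387 with an estimated correlation). CASP10 was lower in C10KO than in C8KO cells, at -0.82 ± 0.16 (adjusted p = 0.000938), and CASP8 differed by 0.07 ± 0.08 (adjusted p = 0.695).

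The knockouts also shared calls against control. In media 108 genes were higher and 26 lower in both, against 2.06 and 0.57 for independent calls, under PMA alone 707 and 483 (114.8 and 86.16), with LPS 256 and 186 (27.96 and 14.73), with TNF 88 and 76 (4.818 and 2.491) and with ZCT 103 and 91 (7.367 and 5.211). Opposite calls numbered 10, 49, 8, 2 and 7. Both knockouts were compared with the same control libraries, which independent calls do not allow for. The Pearson r between the knockout differences was 0.486 to 0.519 over conditions, and simulated unchanged knockouts against shared controls gave 0.481 to 0.514. The covariance was 0.764 to 1.15 and that of the simulations 0.381 to 0.447, higher than simulated in each condition. The simulated knockouts were unchanged, so a difference particular to the control cells would also raise the covariance. The total of same-direction calls, 2124, was 4299 without control PMA+ZCT replicate 1. In all 5 conditions 41 genes were higher and 4 lower in both knockouts, and 1 was opposite. SNRPN, MAGED1, DNAJC15, SNX25 and WWC2 were higher in both averages, at 10.17 ± 0.36 for WWC2 in C10KO and 10.27 ± 0.36 in C8KO cells. ADAM12 was lower in both, at -3.11 ± 0.21 in C8KO cells. SNX25 and WWC2 lie in a chromosome 4 segment, described below, that was higher in both knockouts. A copy-number difference of the control cells is a candidate explanation there, so these 2 genes need not reflect the knockouts. The other shared calls could also come from the control cells, which these comparisons cannot tell from an effect of both knockouts.

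Responses to PMA themselves differed between C10KO and control cells, as tested by interaction terms. For PMA against media, 293 genes responded differently, 147 with a higher and 146 with a lower term in C10KO cells. Interferon-stimulated genes responded less in 24 of 31 cases (27 adjusted over the list alone, adjusted p = 0.00576 with an estimated correlation), with IFIT1 at -4.27 ± 0.53 and OAS1 at -3.79 ± 0.44. Cell cycle genes, most of which fell in control cells, had higher terms in 10 of 25 (17 adjusted over the list alone, adjusted p = 0.000622 with an estimated correlation). PCNA (1.26 ± 0.19) and MYBL2 (1.07 ± 0.14) thus fell less in C10KO cells. CD36 responded more (4.08 ± 0.28), but it was lower in C10KO than in control cells in media, and its term includes that lower start. The count fell to 193 without control PMA replicate 1, to 144 and 134 without control media replicates 1 and 2, and to 159 and 156 without C10KO media replicates 1 and 2. Stimulation as the mean of LPS, TNF and ZCT against media, added after the data were seen and free of PMA-alone libraries, gave 724 genes. Interferon-stimulated genes again responded less in 20 of 31 cases (25 adjusted over the list alone, adjusted p = 0.0173 with an estimated correlation), with OAS1 at -2.99 ± 0.41. Cell cycle genes had higher terms in 22 of 25 (24 adjusted over the list alone, adjusted p = 8.51e-06 with an estimated correlation), with CCNE2, cyclin E2, at 2.50 ± 0.22 and PCNA at 1.55 ± 0.17, a smaller fall for PCNA. TNF and CCL2 had higher terms, at 2.52 ± 0.52 and 2.45 ± 0.50. They were the 1 changed member each of 17 inflammatory cytokines and 17 chemokines, and the chemokine list had a median of -0.39. CCL2 was lower in C10KO than in control cells in media, and its term includes that lower start. That count was 372 to 402 without each of the 4 media libraries in turn and 1175 and 1110 without control PMA+ZCT replicates 1 and 2.

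For the stimuli against PMA alone, C10KO interaction terms were few. With LPS 47 genes differed, 3 of 25 cell cycle genes among them (11 adjusted over the list alone, adjusted p = 0.00843 with an estimated correlation): CDK1, the mitotic kinase (1.04 ± 0.19), CCNA2 (0.74 ± 0.14) and MYBL2 (0.80 ± 0.14), and the haem-degrading enzyme HMOX1 responded more (1.24 ± 0.24). That count was 2 and 18 without C10KO PMA+LPS replicates 1 and 2, 8 and 9 without control PMA+LPS replicates 1 and 2, 24 without control PMA replicate 1 and 76 without C10KO PMA replicate 2. With TNF 2 genes differed, HMGCS1 and SNHG14, named after their values were seen. SNHG14 went from 2.39 ± 0.144 CPM in control PMA alone to 0.0256 ± 0.0361 with TNF, and from 29.6 to 21.9 in C10KO cells. Whether its low control level under PMA alone belongs to the opposite-strand difference of those libraries was not tested. The count was 3 to 6 without single libraries, 4 without control PMA replicate 1 or C10KO PMA replicate 1 or 3, 5 without C10KO PMA replicate 2 or control PMA+TNF replicate 1, and 6 without C10KO PMA+TNF replicate 2. With ZCT 8 genes differed, including CCNA2 (0.77 ± 0.14), KIF18B (0.80 ± 0.14) and PGRMC2 (-1.59 ± 0.20). The ZCT count was 2273 without control PMA+ZCT replicate 1, 15 without C10KO PMA replicate 1 or control PMA replicate 3, and 16 without C10KO PMA replicate 2. ZCT over TNF, added after the data were seen, differed in 3 genes (NICN1 higher, PGRMC2 and SMG8 lower, named after their values were seen). The count was 1305 without control PMA+ZCT replicate 1, 1 without control PMA+TNF replicate 1, and 5 without C10KO PMA+TNF replicate 2, C10KO PMA+ZCT replicate 1 or control PMA+ZCT replicate 2.

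In C8KO cells the response to PMA differed from that of control cells in 2621 genes, 1162 higher and 1459 lower. Interferon-stimulated genes responded less in 28 of 31 cases (29 adjusted over the list alone, adjusted p = 0.00864 with an estimated correlation), with OAS2 at -9.72 ± 0.63, as did CXCL10 (-9.22 ± 0.66). OAS2 and CXCL10 were higher in C8KO than in control cells in media, and their terms include that higher start. Cholesterol genes, 10 of which fell in control cells, had higher terms in 16 of 18 (also 16 adjusted over the list alone, adjusted p = 0.00161 with an estimated correlation), with IDI1 at 2.63 ± 0.20. Most of these genes, IDI1 included, were lower in C8KO than in control cells in media, and the terms include that lower start. NF-kB targets responded less in 8 of 24 cases (also 8 adjusted over the list alone, adjusted p = 0.646 with an estimated correlation). That count was 1698 without C8KO media replicate 2 and 1724 and 1688 without control media replicates 1 and 2. With LPS, TNF and ZCT against PMA alone, 1797, 1567 and 1932 genes differed, interferon-stimulated genes responding more in 25 of 31 cases with LPS (27 adjusted over the list alone, adjusted p = 0.0366 with an estimated correlation). IFIT1 was at 5.62 ± 0.52 with LPS and 5.47 ± 0.52 with TNF. CSF1R was at 1.97 ± 0.18, 2.09 ± 0.18 and 1.98 ± 0.18. These 3 sets and the response to PMA rest on the C8KO PMA-alone libraries that differ in whole chromosomes. Without C8KO PMA replicate 2 the 3 sets numbered 2728, 2491 and 2914. Leaving out each library of the stimulated groups in turn gave 999 to 1090, 798 to 917 and, for ZCT, 1193 and 1214 without C8KO PMA+ZCT replicates 2 and 1 and 3625 without control PMA+ZCT replicate 1.

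Without PMA-alone libraries, C8KO cells still differed in the response to stimulation. The mean of the 3 stimuli against media, added after the data were seen, differed in 249 genes, 66 higher and 183 lower. Cholesterol genes had higher terms in 10 of 18 cases (15 adjusted over the list alone, adjusted p = 9.49e-06 with an estimated correlation), with INSIG1 at 2.76 ± 0.29 and HMGCS1 at 2.13 ± 0.16. Most of this list, INSIG1 included, was lower in C8KO than in control cells in media, and the terms include that lower start. Interferon-stimulated genes responded less in 10 of 31 (25 adjusted over the list alone, adjusted p = 0.0227 with an estimated correlation), with OAS1 at -3.46 ± 0.40, and CXCL10, MMP9 and TNFAIP3, which were higher in C8KO cells in media, responded less, at -9.19 ± 0.62, -5.27 ± 0.69 and -2.20 ± 0.33. Each media library left out in turn gave 116 to 121 genes. ZCT over TNF differed in 0 genes in edgeR, with 589 at an unadjusted p under 0.05 and 4 by DESeq2, and in 88 without control PMA+ZCT replicate 1, 4 without its replicate 2 and 0 to 2 without each other library.

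Differences also followed position along chromosomes, a scan chosen after the data were seen. The scan itself set the edges of each segment. The 45 protein-coding genes with a mean log2 CPM of at least 3 between 152779937 and 189963204 on chromosome 4 (GRCh38) had a median log2 fold change of at least 0.74 in both knockouts in each of the 5 conditions. The highest window of 20 genes had a median of 1.12 in C10KO and 1.01 in C8KO cells, where shuffled gene orders reached 0.37 and 0.36. SNX25 lies in the same span and had 0 CPM in all 11 control libraries. In C10KO cells the most extreme window on chromosome 5 between 196871 and 54310582 was at 0.46, and in C8KO cells that on chromosome 7 between 56011051 and 102478907 was at -0.52. The chromosome 7 segment was at -0.52 to -0.41 in the 8 C8KO libraries other than PMA alone, and at -0.12 to -0.04 in the 3 PMA-alone C8KO libraries. In those 3, chromosome medians were 0.59 to 0.86 on chromosome 18 and -0.45 to -0.38 on chromosome 20, and genes up to CASP10 on chromosome 2 were at 0.65 to 1.72 where those from CASP8 onward were at -1.05 to -0.49.

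**Figure D4:**
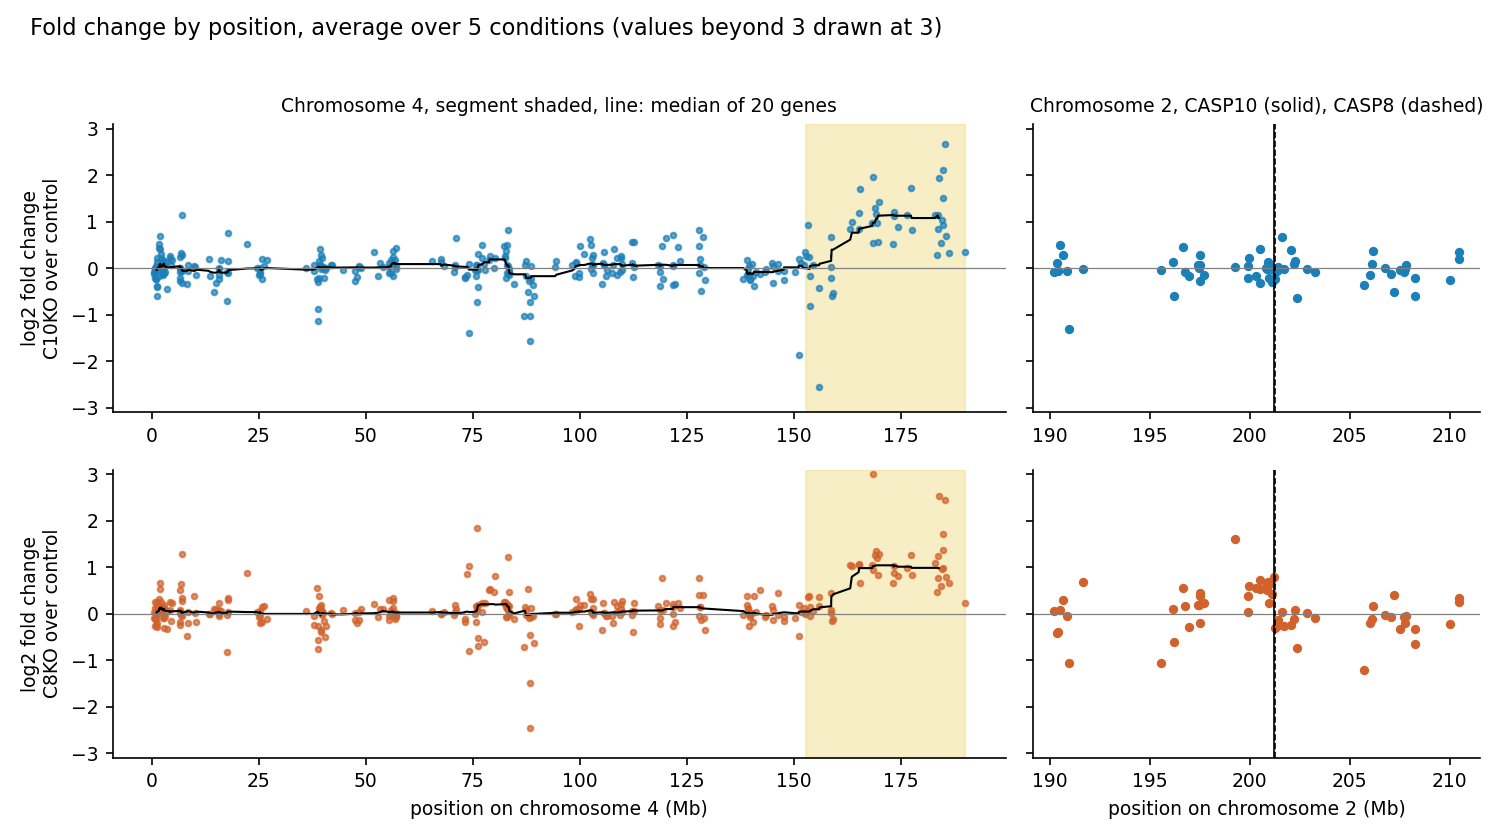
Average log2 fold change over 5 conditions of each gene (points) by position on chromosome 4, with the segment shaded and the median of 20 genes as a line, and on chromosome 2 around CASP10 (solid line) and CASP8 (dashed line), for C10KO (top) and C8KO (bottom). The highest chromosome 4 window was 1.12 in C10KO and 1.01 in C8KO cells.

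**Figure D5:**
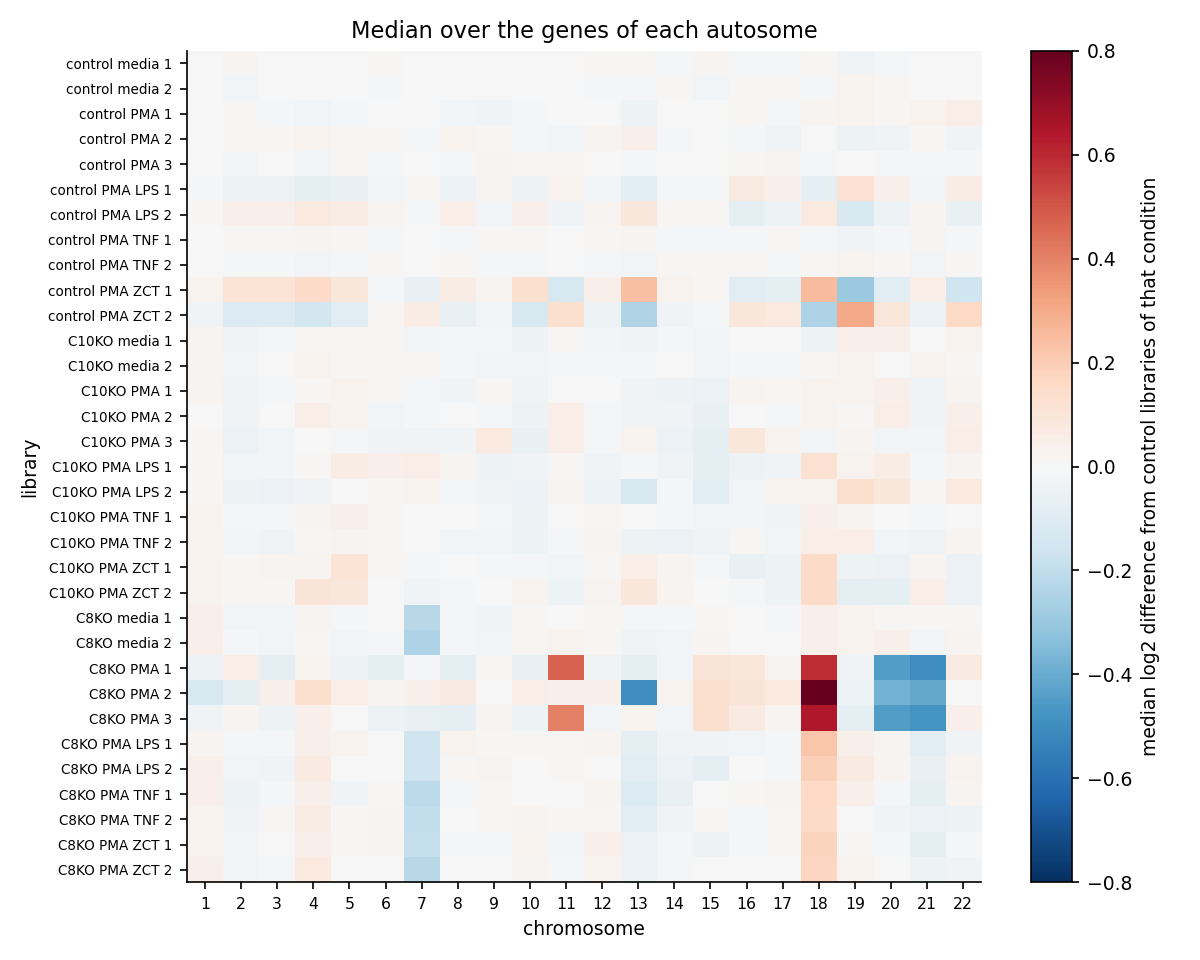
Median log2 difference from the control libraries of the same condition over the genes of each autosome (horizontal) in each of the 33 libraries (vertical), as colour. The 3 C8KO PMA-alone libraries reach 0.59 to 0.86 on chromosome 18.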

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

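The tests of batch and strand counting, of the chromosome shifts and of the chromosome 4 segment were chosen only after the result was seen. So were the interaction comparisons with stimulation or with ZCT over TNF. Each result given first was singled out because an interaction test found genes whose effect differed between genotypes.

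For C10KO cells, the response to PMA differed in 293 genes (147 higher, 146 lower), that to LPS in 47, that to TNF in 2 and that to ZCT in 8. With stimulation as the mean of 3 stimuli against media 724 genes differed, and with ZCT over TNF 3 did. For C8KO cells, the response to PMA differed in 2621 genes, that to LPS in 1797, that to TNF in 1567, that to ZCT in 1932 and that to stimulation against media in 249. Among the genes behind these values are IFIT1 and OAS1 of the interferon list, MCM7 and PCNA of the cell cycle list, and IDI1 of the cholesterol list.

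All 9 PMA-alone libraries held more noncoding and opposite-strand transcripts than the other 24, in all 3 genotypes. Depth as the cause is argued against by thinning all libraries to 1 total, after which the PMA-alone libraries still had at least 16019 genes with 10 or more counts and the others at most 14500. Counting by strand of libraries that do not keep strand may account for it: opposite-strand genes that cover each other, such as MGAT2, had nearly equal counts in these libraries, within 0.117 on the log2 scale, and lay beyond 5.7 elsewhere. PMA exposure as such is argued against for the opposite-strand counts, because the stimulated libraries also had PMA overnight. With the media libraries they held 438 to 638 CPM of covered genes, against 6864 to 7808 here. A PMA effect that each of the 3 stimuli undid within 3 h was not tested. A batch cannot be told apart from the PMA-alone condition. The lowest noncoding share of the 9, 2.05%, lies above all others, but the 9 are a single condition. That condition also has another file header and at most 31955099 counts per library against at least 51856023. Between control cells with PMA alone and after stimulation, 71.1% of covered genes and 3.26% of genes without overlap were at least 4-fold higher with PMA alone, as were 14.3% of those within an opposite-strand gene and 11.1% of those with other overlap, so rises outside covered genes stay open.

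The 3 C8KO PMA-alone libraries were shifted along whole chromosomes relative to the other 8 C8KO libraries, with chromosomes 18, 20 and 21 standing out. The PMA-alone batch is argued against by C10KO PMA-alone libraries, whose chromosome 18 medians reached 0.03 at most against at least 0.59 here. As the only cause, a response of the same C8KO cells to PMA is argued against by the chromosome 7 segment. It was low in the other 8 C8KO libraries (-0.52 to -0.41) and at -0.12 or above in these 3. A part that follows PMA stays open: chromosome 18 was at 0.04 in C8KO media libraries and 0.15 to 0.22 in those with stimuli. Genes up to CASP10 on chromosome 2 were likewise at 0.02 to 0.09 and 0.25 to 0.37. The SD over autosome medians was at least 0.224 here and at most 0.069 in the other 8. Control PMA+ZCT replicates 1 and 2 had an SD of 0.13, where shuffles reached 0.068, so smaller shifts also occurred between control replicates. Cells of another clone or karyotype may account for the larger shift here. Whether the low ISG15 of C8KO cells under PMA alone belongs to caspase-8 or to such cells stays open.

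Most genes of the chromosome 4 segment were higher in both knockouts. A response to losing either caspase, gene by gene, is argued against by their order along the chromosome, since windows of 20 neighbouring genes reached 1.01 or more in both knockouts and shuffled orders 0.37 at most. A copy-number difference of the control cells is a candidate explanation, as the segment median was at least 0.74 in each of the 10 comparisons. SNX25, a gene in the segment singled out after its values were seen, had 0 CPM in all 11 control libraries, which a gain in both knockout lines alone would not give. A gain in the knockout lines beside a loss in control cells stays open.

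For C10KO against control in PMA, 1621 genes changed and the highest of the other splits of the 6 libraries gave 10, and for C8KO 5434 and 49, but 10 splits are too few for a share under 0.05. For the averages, 1 of 100 splits, the real 1, gave as many genes. The real counts were 3728 against at most 952 for C10KO, 3690 against 712 for C8KO and 3299 against 1584 for C10KO against C8KO. A share of 1 in 100 is the lowest these splits can give. Mixed splits also widen the spread within groups, so fewer calls there follow wherever libraries of a group resemble each other. The splits thus cannot tell a knockout effect from another difference between the lines.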

How the results depend on the processing

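The fit without 2 libraries that stand apart, the averages without PMA alone, and the comparisons without PMA-alone libraries (TNF against media, LPS and ZCT against TNF, and interactions with stimulation and with ZCT over TNF) were chosen only after the result was seen. No named result called in the main fit or in an alternative reversed direction. In 1 case called in neither, the sign changed when 1 library was left out. Of the named calls, 35 of 217 were lost when 1 library was left out. In the fit to the compared groups alone, 25 of 223 named results were weaker. Counts under RLE factors stayed within 1.5 times of those reported. Over alternatives and single libraries left out, 455 counts and correlations stayed within 1.5 times or their spread and 168 moved. The averages, the control response to PMA and the C8KO difference under PMA alone, with ISG15 lower, stayed within 1.5 times with each library left out (3234 to 4878 and 3140 to 4767 for the averages against control, 9469 to 11258, and 4371 to 5838). Counts with 2 libraries per group depend most on each library: leaving out 1 leaves a single library, assumed to vary like other groups, and fewer degrees of freedom. No comparison was refitted at lower depth, and with 2 libraries per group 2-fold changes were recovered in 10% of simulated cases. Except for those left-out libraries, the cause was not tested.

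With DESeq2, C10KO differed in 519 genes in media, 2452 with PMA, 1317 with TNF and 1877 with ZCT, and C8KO in 719 in media, 1682 with LPS, 809 with TNF and 990 with ZCT. C10KO interactions were 835 with PMA, 460 with LPS, 98 with TNF, 225 with ZCT, 1401 with stimulation and 10 with ZCT over TNF, and C8KO interactions 2738 with LPS, 2474 with TNF, 3029 with ZCT, 625 with stimulation and 4 with ZCT over TNF. LPS against TNF gave 45, ZCT against TNF 1418, and shared calls of the knockouts 3625.

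Fitting the libraries of the compared groups alone gave 5705 for ZCT in control cells. C10KO gave 408 in media, 354 with PMA, 1633 with TNF and 4 with ZCT, and C8KO 772, 3314, 988 and 19 in these conditions and 2037 with LPS. C10KO interactions were 96, 24, 14 and 2 with PMA, LPS, TNF and ZCT and 1 with ZCT over TNF, and C8KO interactions 1193, 1036 and 393 with LPS, TNF and ZCT and 616 with stimulation. LPS against TNF gave 23 and ZCT against TNF 0 (228 in edgeR with all libraries and 1418 by DESeq2). Genes called in all 5 conditions were 3 for C10KO and 10 for C8KO.

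Without 2 libraries that stand apart, C8KO with ZCT gave 1410, ZCT against TNF 22 and shared calls of the knockouts 3471. C10KO interactions gave 647 with PMA, 272 with LPS, 5 with TNF and 1593 with stimulation, and C8KO interactions 668 with stimulation and 4 with ZCT over TNF. Without the filter on low counts, C10KO interactions were 26, 6 and 5 with LPS, TNF and ZCT, and ZCT against TNF gave 30. With a replicate block, the C10KO interaction with ZCT gave 14. Of 213 list calls across comparisons, 38 held with an estimated correlation, 182 were called by fry and 211 with the block.

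Leaving out 1 library in turn gave these ranges. In control cells LPS gave 2785 to 4510, TNF 3722 to 5615, LPS against TNF 1 to 3 and ZCT against TNF 1 to 4237. C10KO gave 109 to 133 in media, 932 to 1714 with PMA, 907 to 1292 with LPS, 382 to 443 with TNF and 578 to 3555 with ZCT. C8KO gave 232 to 250 in media, 237 to 337 with LPS, 163 to 174 with TNF and 197 to 1885 with ZCT. C10KO interactions were 134 to 380 with PMA, 2 to 76 with LPS, 3 to 6 with TNF, 8 to 2273 with ZCT, 372 to 1175 with stimulation and 1 to 1305 with ZCT over TNF. C8KO interactions were 1688 to 3436 with PMA, 999 to 2728 with LPS, 798 to 2491 with TNF, 1193 to 3625 with ZCT, 116 to 368 with stimulation and 0 to 88 with ZCT over TNF. C10KO genes called in all 5 conditions were 52 to 101, shared calls of the knockouts 1559 to 4299, and the median C10KO correlation between conditions 0.136 to 0.194. The highest values with ZCT came without control PMA+ZCT replicate 1.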

Other observations

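The tests of a break at CASP8 and of the response to PMA were written before their results were seen. The genes of the next 2 paragraphs were picked by eye from those the naming rule allows, after their values were seen.

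In C10KO cells with LPS, PHGDH, the first enzyme of serine synthesis, was higher by 1.70 ± 0.19 and PSAT1, the next, by 0.95 ± 0.14. MT-ND5 (-1.19 ± 0.19) and MT-ATP8 (-1.09 ± 0.19) were lower, among 7 of 13 mitochondrially encoded mRNAs (10 adjusted over the list alone, adjusted p = 0.277 with an estimated correlation). Averaged over conditions, PHGDH was at 0.96 ± 0.08 and MT-ND5 at -0.30 ± 0.08.

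CARD16, a caspase-1 inhibitor, was higher by 1.61 ± 0.21 in C10KO and 1.97 ± 0.21 in C8KO cells on average, and the death ligand TNFSF10 was at -1.19 ± 0.23 and -0.81 ± 0.23. In C8KO cells SPRED1 was higher by 8.06 ± 0.51, CLDN5 by 8.05 ± 0.41, the costimulator CD80 by 3.02 ± 0.52 and the pyroptosis effector GSDME by 2.46 ± 0.60. CCRL2 (-3.90 ± 0.38) and CD226 (-2.49 ± 0.18) were lower.

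In C8KO cells, genes on the CASP10 side of CASP8 on chromosome 2 were higher and those from CASP8 on were not. A hypothesis is a rearrangement with a break near the site targeted in CASP8. The step between the medians of the 12 genes on each side was 0.78 in the C8KO average, and 0.102% of 8860 positions, 9 of them, had a step as large, so a break there may account for it. The step was 1.97 under PMA alone but 0.28 in media, 0.38 with LPS, 0.49 with TNF and 0.45 with ZCT, so the PMA-alone libraries carry much of the average. It was 0 in the C10KO average. CASP10, at 0.78 ± 0.16, lies on the higher side. The PMA-alone libraries are shifted along other chromosomes too, so a clone difference stays open.

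A weaker response to PMA as a whole was a hypothesis for the higher cell cycle genes and lower interferon genes of C10KO cells. The test took 1680 genes changed at least 4-fold by PMA+TNF over media in C8KO cells (mean log2 CPM of at least 1). Their median ratio of the C10KO to the control log2 fold change was 0.978, above the 0.9 set as the bound. A general weakening of the PMA+TNF response is thus argued against for these genes. Genes that responded less in both knockouts can fall outside this set, so a weakening there was not tested. The ratio was 0.993 for the 1046 genes that rose and 0.945 for the 634 that fell.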
